A study of Mus musculus with 7 samples.

How the data were processed

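Messenger RNA was sequenced from G1E-ER4 cells in 7 libraries. The labels put 1 library at 0 h before differentiation, 3 at 24 h of differentiation and 3 at 24 h of differentiation with DTPA, and call the replicates biological. Per the labels' protocols, total RNA was extracted, and libraries were made with the Illumina TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The submitters' processing notes name Trimmomatic 0.33 for read trimming, FastQC for read quality, HISAT2 2.1.0 for alignment, featureCounts for counting and edgeR, with the mouse build mm10. The annotation release, the strand setting of the counting, the treatment of reads with several matches and the gene lengths were not given in the sources used here.

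The deposited values are TPM, 1 value per gene symbol and library, scaled to the same total in each library. TPM divides reads by gene length and by the library's total, so a few abundant genes that rise lower the values of all others. Each table held 55487 rows. There were 114 symbols that stood on more than 1 row, together 234 rows, and their values were summed, which left 55367 symbols. Between 72.3% and 73.7% of the rows were at 0 in a library.

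TPM keeps no depth by itself. The value of 1 read was estimated from the low values, multiplied by the exon length of each gene in GENCODE M21, which is on GRCm38, the assembly also called mm10. There were 53170 symbols with such a length, and they held 98.6% to 98.7% of the TPM. With that step, 98.9% to 99.4% of the tested low values in a library lay within 0.1 of a whole number of reads. The estimated depth was 17.58 M reads assigned to genes in the 0 h library, 17.67 to 18.6 M in the controls and 19.79 to 21.19 M under DTPA. In a gene of 2 kb, 1 read was worth 0.0696 to 0.0857 TPM. On simulated libraries the estimate of the depth was off by at most 0.004%. The same exon lengths made and read those libraries, so the simulation does not test whether the submitters used these lengths. Within each group at 24 h, pairs of libraries differed by more than counting noise, with a mean chi-square per gene of 3.38 to 11.3 where counting alone gives 1, so no library was counted as a copy of another.

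All tests were made with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a moderated variance that follows the mean (eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 fold change is on that scale, which understates the change of low genes. DTPA was compared with control at 24 h in the 6 libraries of that time, over genes with at least 1 TPM in at least 3 libraries. Differentiation was taken from a fit of all 7 libraries in 3 groups, over genes with a mean of at least 1 TPM at 0 h or in the controls. The single 0 h library was there assumed to vary like the other groups, and a gene was called when its log2 fold change was also at least 1 in size. A gene listed at 0 in all libraries of 1 group is described by its values and not by a fold. Exact two-sided permutation tests were made for 3 single genes, and 3 against 3 libraries cannot give a p under 0.1.

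There were 30 gene lists, with 647 written members, of which 642 matched a row, 1 of them through a synonym. Hbb-b1, Hbb-b2 and Ahsp matched no row, and 2 others named the same gene as another member. Lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. For differentiation, the median log2 fold change of a list was set among the medians of 10000 random lists of the same size matched on mean expression, which describes these libraries only. The named genes are all detected zinc transporters, metallothioneins and Mtf1, then the 10 called genes with the largest rise and the 10 with the largest fall in each of the 2 main comparisons (mean of at least 5 TPM in the higher group, no overlap of libraries), and up to 4 called members of each list with the largest change. Unnamed predicted genes among them may be counted instead of named. A few genes that the rule takes are not reported here. The groups, tests, lists, alternatives and this rule were fixed before the data were examined.

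The fits and list tests were tested on simulated data with 200 changed genes. For DTPA against control, 10782 genes were tested, and 72.7% of genes changed 1.5-fold, 86.2% of those changed 2-fold and 90.6% of those changed 4-fold were recovered, with 3.57% of the calls on unchanged genes. For control at 24 h against 0 h, 10853 genes were tested, and 0% of genes changed 1.5-fold, which the minimum fold excludes, 41.5% of genes changed 2-fold and 89.2% of those changed 4-fold were recovered, with 2.3% of the calls on unchanged genes. The simulated 0 h library was drawn with the same spread as the others, so the simulation does not test the assumption that it varies like them. The alternatives were other pseudocounts, filters, scalings (without globin genes, median-of-ratios size factors, quantile normalization), variance models, list tests and fold minimums, a replicate block, fits without each library at 24 h, and voom on the estimated reads, which was added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Coordinates are from GENCODE M21 on mm10. Because the strand setting of the counting is not given, reads from genes that overlap on opposite strands may not be told apart, and near-identical genes may share reads in a way that the sources used here do not describe.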

Results

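The series measured gene expression during erythroid differentiation with and without zinc restriction, and its title names the zinc importer ZIP10, encoded by Slc39a10. G1E-ER4 is a mouse erythroid progenitor line that lacks functional GATA1 and carries GATA1 fused to the ligand-binding domain of the estrogen receptor, so that estradiol starts erythroid maturation. Differentiation was induced with 100 nM β-estradiol for 24 h. Zinc was restricted with 50 µM DTPA, a metal chelator that binds zinc strongly, from the start of differentiation. There were 3 control libraries and 3 DTPA libraries at 24 h and 1 library of undifferentiated cells at 0 h, which has no replicate. Estimated depths were 17.58 to 21.19 M reads, and 10904 to 11268 genes reached 1 TPM in a library. Correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.988 to 0.990 between libraries of a group and 0.947 to 0.951 between control and DTPA. The 0 h library correlated at 0.813 to 0.816 with the controls and at 0.761 to 0.767 with the DTPA libraries. The first principal component held 68.5% of the variance and ran from the 0 h library through the controls to the DTPA libraries. The second held 22.6% and parted the controls from the DTPA libraries, with the 0 h library on the DTPA side.

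Zinc restriction was first read in the genes that handle zinc. The metallothioneins Mt1 and Mt2, small proteins that bind zinc and whose transcription zinc induces, collapsed under DTPA. Mt2 went from 2752 ± 153 TPM (SD, n = 3) in the controls to 12.6 ± 0.992 TPM, a log2 fold change of -7.66 ± 0.0642 (SE, limma adjusted p = 2.27e-09). Mt1 went from 2465 ± 273 to 195 ± 10.2 TPM, a log2 fold change of -3.65 ± 0.0829 (adjusted p = 1.01e-07). The importer gene Slc39a10 moved the other way, from 1.16 ± 0.108 TPM in the controls to 15.5 ± 0.39 TPM under DTPA, a log2 fold change of 2.94 ± 0.0873 (adjusted p = 2.46e-07). Its value was 37.3 TPM at 0 h, so it fell with differentiation by 4.15 on the log2 scale (adjusted p = 8.52e-07) and lay between the 0 h and the control values under DTPA. The estimated reads behind Slc39a10 were 37 to 46 per control library, 643 to 697 per DTPA library and 1343 at 0 h. The exact permutation test gave p = 0.1 for each of Slc39a10, Mt1 and Mt2, which is the smallest p that 3 against 3 libraries allow. Slc39a10 lies on chromosome 1 from 46807544 to 46892852 on the minus strand, and Mt2 and Mt1 lie on chromosome 8 from 94172664 to 94173568 and from 94179082 to 94180327 on the plus strand; the values sum over all exons of each protein-coding gene.

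**Figure D1:**
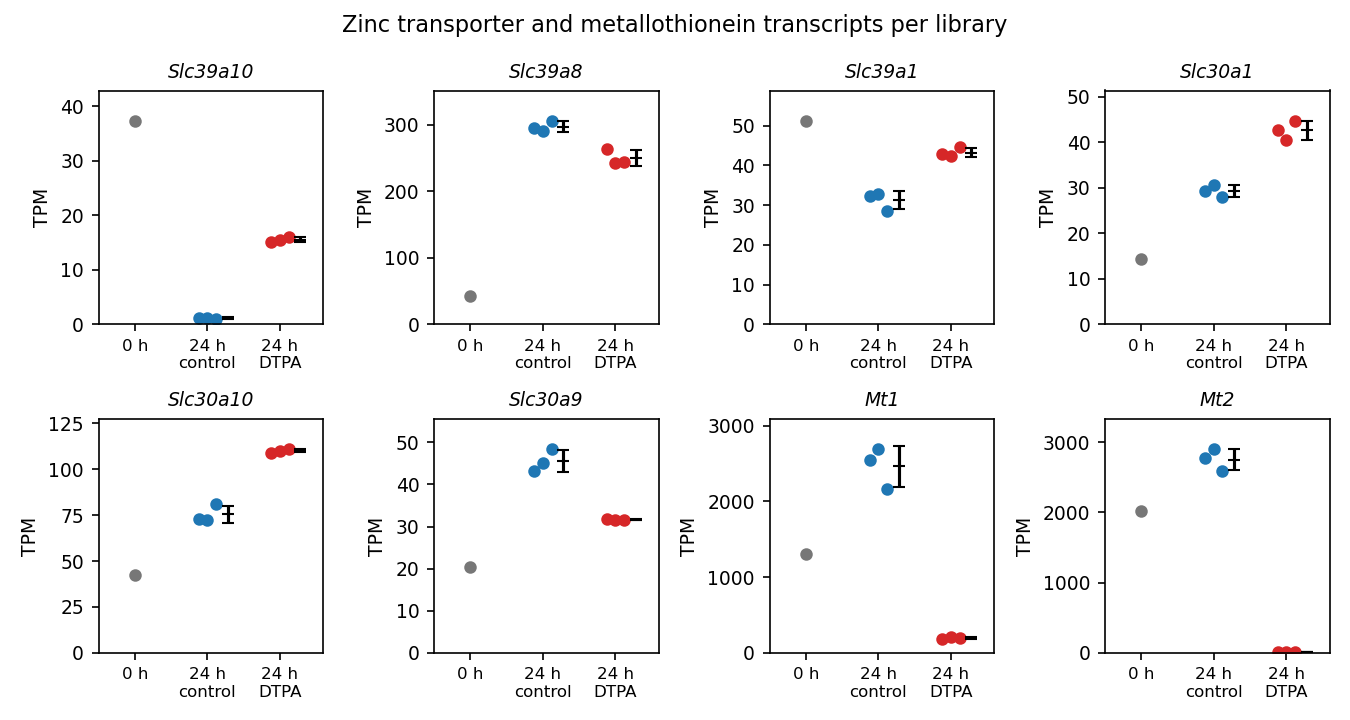
TPM of 8 zinc genes in each library at 0 h (grey, 1 library), in 24 h controls (blue, 3 libraries) and under DTPA at 24 h (red, 3 libraries), with each axis starting at 0; black bars give the mean and SD of 3 libraries. Slc39a10 stood at 37.3 TPM at 0 h, 1.16 in the controls and 15.5 under DTPA, and Mt2 at 2752 in the controls and 12.6 under DTPA.

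Other zinc transporters changed by much less than Slc39a10. Of the 9 tested ZIP importers, 2 rose, 2 fell and 5 did not pass, with the same counts when adjusted over the list alone. Slc39a1, a plasma membrane importer, rose from 31.3 ± 2.34 to 43.2 ± 1.17 TPM (adjusted p = 5.39e-04). Slc39a3 fell from 5.71 ± 0.751 to 3.11 ± 0.783 TPM (adjusted p = 0.00643). Slc39a8, which carries zinc and other metals and was the most abundant importer transcript at 24 h, fell from 298 ± 7.83 to 250 ± 11.7 TPM, a log2 fold change of -0.25 (adjusted p = 0.00217) that did not pass under quantile normalization (-0.09, adjusted p = 0.146). Log2 fold changes of Slc39a6, Slc39a7, Slc39a9, Slc39a11 and Slc39a13 were 0.11, 0.36, -0.01, -0.02 and 0.08, none past the threshold, although Slc39a7 passed without the variance trend (adjusted p = 0.0106). Exons of Slc39a9 and Slc39a13 overlap those of Erh and Psmc3 on the other strand. The list as a whole did not pass (camera adjusted p = 0.271).

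All 7 tested ZnT genes changed, 3 upward and 4 downward, also when adjusted over the list alone. Slc30a1, the main zinc exporter of the plasma membrane, rose from 29.3 ± 1.38 to 42.6 ± 2.12 TPM (adjusted p = 1.62e-04), and Slc30a10, best known as a manganese exporter, rose from 75.4 ± 4.75 to 110.0 ± 0.848 TPM (adjusted p = 7.21e-05). Slc30a7 rose by 0.41 on the log2 scale. Slc30a9 went from 45.5 ± 2.59 to 31.6 ± 0.138 TPM (adjusted p = 1.16e-04), and Slc30a5 from 29.7 ± 1.73 to 20.4 ± 1.32 TPM (adjusted p = 3.99e-04). Slc30a2 and Slc30a6 had log2 fold changes of -0.67 (adjusted p = 0.0214) and -0.31 (adjusted p = 0.0176). The call of Slc30a2 was lost without DTPA replicate 1 (adjusted p = 0.0558) or 2 (0.0773), and that of Slc30a6 under median-of-ratios scaling (0.0571), quantile normalization (0.0743) and without control replicate 1 (0.0536) or 3 (0.0528) or DTPA replicate 1 (0.0522) or 3 (0.0597). The median log2 fold change of the list was -0.31, its mean -0.08 and the direction of its test upward, and it did not pass (camera adjusted p = 0.844). The median was 0.05, 0.01 and 0.09 without control replicate 1, 2 or 3, and 0.05 with a filter of 5 TPM. Slc30a10 shares 533 bp of exon with Gm2061 on the other strand.

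All 3 tested genes of the metallothionein list fell, also when adjusted over the list alone, with a median log2 fold change of -3.65. The third, Mtf1, which encodes the zinc-sensing activator of metallothionein genes, went from 27.8 ± 1.02 to 19.3 ± 1.33 TPM (adjusted p = 3.63e-04); it shares 721 bp of exon with 1110065P20Rik on the other strand. The list fell (camera adjusted p = 0.0089; adjusted p = 0.247 with an estimated correlation). Of 15 tested zinc-dependent enzymes, 4 rose, 6 fell and 5 did not pass (4 and 7 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.923), with a median of 0.01, a mean of -0.07 and a downward test. Car1, a carbonic anhydrase of early erythroid cells, rose from 88.5 ± 6.47 to 462 ± 37.4 TPM (adjusted p = 2.84e-07). Alad, the zinc enzyme of the second step of heme synthesis, fell from 1016 ± 30.9 to 317 ± 21.5 TPM (adjusted p = 3.86e-07). Car13 fell by 1.18 and Car3 rose by 0.76 on the log2 scale.

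DTPA changed the transcriptome broadly at 24 h. The 10 largest rises included the embryonic globin genes Hbb-bh1, Hbb-y and Hba-x, and the 10 largest falls included Mt2, Mt1, the erythroid genes Hemgn and Slc4a1 and 5 cell cycle genes. Among 11147 tested genes, 2415 were higher and 4059 lower under DTPA (limma, adjusted p under 0.05), of which 392 and 580 changed at least 2-fold. The libraries of the 2 groups did not overlap in 7249 genes, 65% of those tested, where chance gives 10%. The balance of higher and lower calls depended on the scaling. The median log2 fold change of all genes was -0.09 on the deposited scale, -0.0008 with median-of-ratios size factors, which gave 3047 higher and 3315 lower genes, and 0.01 with quantile normalization, which gave 3201 and 3106. The share of calls that were higher went from 37.3% to 47.9% and 50.8%.

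Among the 10 largest rises, 3 were embryonic globins, given with the globins. Alpk3, which encodes a kinase known from muscle, rose from 3.07 ± 0.0907 to 80.7 ± 6.9 TPM, a log2 fold change of 4.32 (adjusted p = 4.95e-08). Cpz, encoding carboxypeptidase Z, rose from 10.8 ± 0.429 to 105 ± 4.25 TPM, and Mgarp, encoding a mitochondrial protein, from 12.6 ± 1.69 to 103.8 ± 2.44 TPM, with log2 fold changes of 3.17 and 2.96. Gip, the gene of a gut hormone, rose from 2.38 ± 0.62 to 30.4 ± 2.6 TPM. Hbb-bh0, annotated as a pseudogene with 129 bp of exon, was listed at 0 in the 3 controls and at 4.45, 7.97 and 14.03 TPM in the DTPA libraries, and the other 2 were unnamed genes. Among the 10 largest falls, Slc4a1, the anion exchanger band 3 of the red cell membrane, fell from 770.3 ± 3.71 to 73 ± 2.81 TPM, a log2 fold change of -3.38 ± 0.0392 (adjusted p = 8.31e-09). Hemgn, which encodes the erythroid nuclear protein hemogen, fell from 32.5 ± 2.03 to 1.68 ± 0.331 TPM, and Slc52a3, a riboflavin transporter, from 37.3 ± 2.65 to 2.53 ± 0.145 TPM. The remaining genes were Mt2, Mt1 and the cell cycle genes Cdc25c, Kif20a, Mybl2, Mcm5 and Nusap1, with log2 fold changes of -3.43, -3.43, -3.37, -3.34 and -3.31 for these 5. Kif20a shares 1271 bp of exon with Cdc23 on the other strand.

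Globin transcripts shifted toward embryonic genes under DTPA. Hbb-bh1, an embryonic beta-like globin on chromosome 7 from 103841637 to 103843164, rose from 53.7 ± 5.01 to 4319 ± 141 TPM, a log2 fold change of 6.31 ± 0.0661 (adjusted p = 5.97e-09). The embryonic Hbb-y rose from 14.9 ± 0.937 to 312 ± 37.3 TPM, and the embryonic alpha-like Hba-x from 7.25 ± 1.02 to 76.6 ± 11.2 TPM, with log2 fold changes of 4.29 and 3.23. Hbb-bh2 was listed at 0 in the controls and at 2.57, 3.68 and 4.24 TPM under DTPA. The adult alpha genes Hba-a1 and Hba-a2, near-identical copies best read as a sum, fell from 17819 ± 1268 to 12986 ± 483 TPM, a log2 fold change of -0.45 (adjusted p = 7.46e-04). The adult beta genes Hbb-bs and Hbb-bt summed to 31802 ± 1223 and 52380 ± 9738 TPM, a log2 fold change of 0.70 (adjusted p = 0.00197), and the value assigned to Hbb-bt ranged from 4380 to 16392 TPM among the DTPA libraries. Of 9 tested globin genes, 6 rose and 3 fell, also when adjusted over the list alone, with a median of 2.12, the value of Hbb-bt. The median was 1.24 without DTPA replicate 1, 1.06 without DTPA replicate 2, 1.30 without a filter or with a filter of 5 TPM, and 0.76 with a pseudocount of 5. The list rose (camera adjusted p = 0.00981; adjusted p = 0.247 with an estimated correlation), but not under quantile normalization (adjusted p = 0.0546). All globins together held 4.71% to 5.11% of the TPM in the controls and 6.27% to 8.12% under DTPA.

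**Figure D2:**
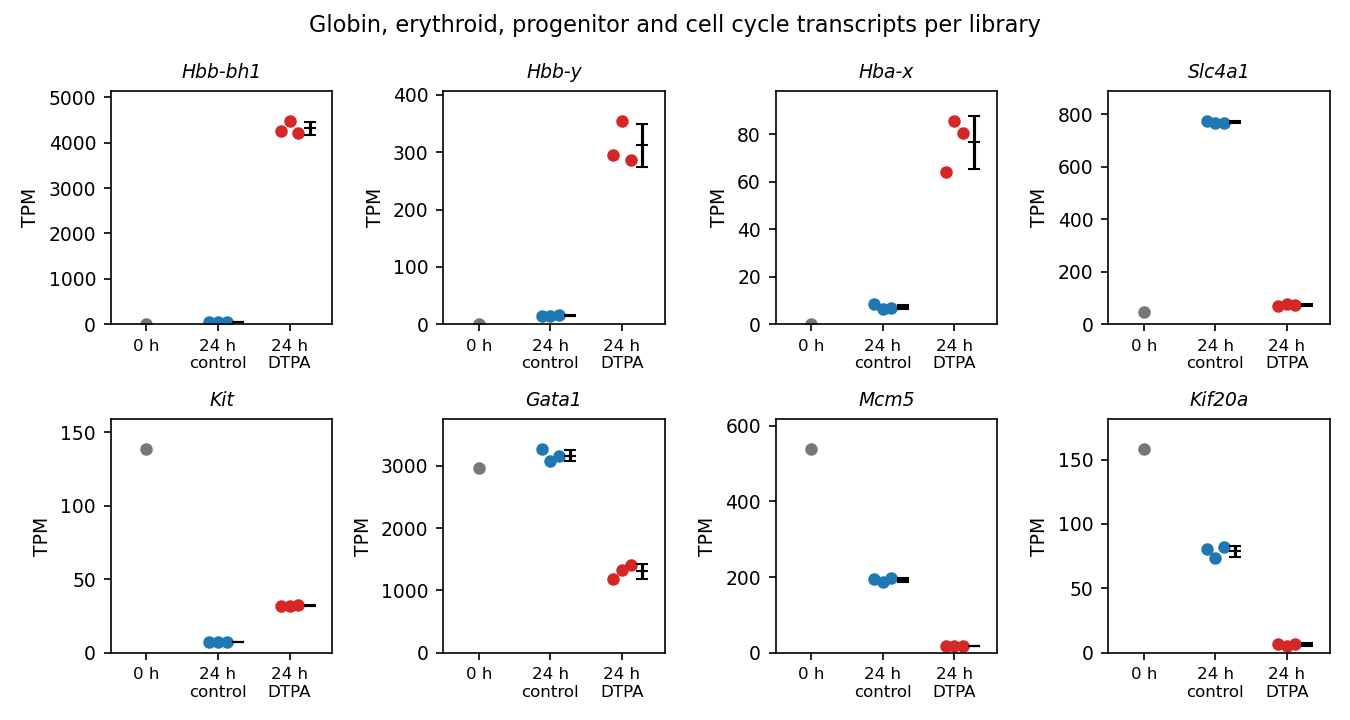
TPM of 8 globin, erythroid, progenitor and cell cycle genes in each library at 0 h (grey, 1 library), in 24 h controls (blue, 3 libraries) and under DTPA at 24 h (red, 3 libraries), with each axis starting at 0; black bars give the mean and SD of 3 libraries. Hbb-bh1 rose from 53.7 to 4319 TPM under DTPA, while Slc4a1 fell from 770.3 to 73 TPM.

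Genes of the erythroid membrane and cytoskeleton were mostly lower under DTPA. Of 22 tested, 5 rose, 15 fell and 2 did not pass (5 and 16 when adjusted over the list alone), with a median of -0.59. Besides Slc4a1, the blood group gene Rhd fell from 20 ± 1.92 to 1.16 ± 0.297 TPM, the actin-bundling dematin gene Dmtn from 98.8 ± 1.95 to 19.8 ± 0.758 TPM, and the tropomodulin gene Tmod1 from 7.34 ± 0.645 to 1.1 ± 0.31 TPM; Tmod1 shares 1287 bp of exon with Tstd2 on the other strand. The list fell (camera adjusted p = 0.0124; adjusted p = 0.401 with an estimated correlation). Of 19 heme synthesis and transport genes, 4 rose, 11 fell and 4 did not pass (5 and 11 when adjusted over the list alone). Alad and the mitochondrial carrier gene Slc25a39 fell by 1.68 and 1.38 on the log2 scale, while Uros, an enzyme of heme synthesis, rose from 55.5 ± 1.2 to 116 ± 1.48 TPM. The heme list did not pass (camera adjusted p = 0.44).

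Of 17 iron uptake and storage genes, 4 rose, 7 fell and 6 did not pass (4 and 8 when adjusted over the list alone; camera adjusted p = 0.982), with a median of -0.11 and an upward test. The mitochondrial iron importer gene Slc25a37 fell from 205 ± 6.22 to 116 ± 6.22 TPM and Pcbp1 by 0.44 on the log2 scale. Tfr2, a transferrin receptor, rose from 13.5 ± 1.23 to 20.9 ± 1.3 TPM. Of 17 erythroid transcription factors, 7 rose, 6 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.44), with a median of 0.05, a mean of -0.10 and an upward test. Gata1 reads, which in this line can also come from the introduced fusion gene, fell from 3164 ± 93.1 to 1305 ± 118 TPM, a log2 fold change of -1.28 (adjusted p = 3.81e-06). E2f2, a cell cycle regulator of erythroblasts, fell from 33 ± 0.867 to 4.66 ± 0.206 TPM, while Gfi1b, a repressor needed for erythroid and megakaryocytic maturation, rose from 510.2 ± 3.64 to 1077 ± 93.7 TPM and Cited2 from 24.3 ± 4.36 to 58.5 ± 2.6 TPM. Of 11 erythropoietin and STAT5 targets, 3 rose, 6 fell and 2 did not pass, also when adjusted over the list alone (camera adjusted p = 0.94). Erfe, the iron-regulating hormone erythroferrone, fell from 43.4 ± 1.62 to 5.53 ± 1 TPM (adjusted p = 8.19e-07), with 357 bp of exon shared with Ilkap on the other strand; Socs3 and Cdc25a fell by 1.05 and 0.91 and Socs1 rose by 0.97 on the log2 scale.

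Progenitor genes were mostly higher under DTPA than in the controls. Of 13 tested, 8 rose, 4 fell and 1 did not pass (8 and 5 when adjusted over the list alone), with a median of 0.64. Kit, the receptor of stem cell factor, rose from 7.41 ± 0.207 to 32.1 ± 0.261 TPM, against 138 TPM at 0 h. The myeloid and lymphoid factor gene Spi1 rose from 13.5 ± 1.16 to 38.6 ± 1.17 TPM, Hhex from 11 ± 0.54 to 27.3 ± 2.14 TPM, and Myb from 0.617 ± 0.085 to 2.85 ± 0.0608 TPM. The list rose (camera adjusted p = 0.0131; adjusted p = 0.247 with an estimated correlation). Megakaryocyte markers were also higher. Of 20 markers, 15 were too low to be tested, and the 5 tested rose, also when adjusted over the list alone, with a median of 1.60, or 0.42 without a filter on low values (camera adjusted p = 5.32e-04; adjusted p = 0.236 with an estimated correlation). The platelet integrin gene Itgb3 rose from 2.18 ± 0.202 to 15.3 ± 0.706 TPM, the von Willebrand receptor gene Gp1ba from 7.17 ± 1.53 to 26.5 ± 2.5 TPM and the granule gene Nbeal2 from 3.71 ± 0.187 to 13.3 ± 1.91 TPM. Gp9 rose from 1.01 ± 0.457 to 3.11 ± 1.6 TPM, a call lost without control replicate 2 (limma adjusted p = 0.0531) or 3 (0.0713) or DTPA replicate 3 (0.0586). It was also lost without a filter on low values (0.061).

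Markers of other blood lineages stayed low. Of the myeloid and mast cell markers, 2 were tested: Hdc rose from 0.483 ± 0.196 to 2.56 ± 0.397 TPM, and Cd68 fell from 2.78 ± 0.0896 to 1.66 ± 0.642 TPM (adjusted p = 0.0427). The call of Cd68 was lost under several settings, among them without each control replicate in turn (adjusted p = 0.0988, 0.0881 and 0.0856) and without DTPA replicate 1 (0.0914) or 2 (0.118). The 1 tested lymphoid marker, Cd79a, rose from 0.547 ± 0.449 to 2.65 ± 0.145 TPM (adjusted p = 0.00166).

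Cell cycle genes fell together under DTPA. All 30 genes of the G1/S and replication list and all 30 of the G2/M and mitosis list fell, also when adjusted over the list alone, with medians of -1.79 and -2.88. The replication helicase genes Mcm5 and Mcm6 fell from 193 ± 5.44 to 18.2 ± 0.633 TPM and from 70.3 ± 2.47 to 7.86 ± 0.346 TPM. Rrm2, a subunit of ribonucleotide reductase, fell from 136 ± 8.89 to 13.3 ± 0.347 TPM, and Uhrf1, which maintains DNA methylation, from 44.7 ± 0.611 to 3.74 ± 0.683 TPM. The mitotic kinesin gene Kif20a fell from 78.7 ± 4.39 to 6.44 ± 0.824 TPM, the spindle gene Nusap1 from 220.4 ± 23.5 to 21.2 ± 1.57 TPM, Birc5, encoding survivin, from 124 ± 2.76 to 11.7 ± 1.23 TPM and Cdca3 from 127 ± 2.06 to 12.8 ± 1.14 TPM. Both lists fell by camera, G1/S with adjusted p = 1.5e-14 and G2/M with adjusted p = 6.73e-18. Neither passed with adjusted p = 0.195 and adjusted p = 0.233 with an estimated correlation.

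Targets of p53 rose and several stress programs fell. Of 19 tested p53 targets, 12 rose, 3 fell and 4 did not pass, also when adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.0089; adjusted p = 0.233 with an estimated correlation). The proapoptotic gene Bbc3 rose from 91.5 ± 14.9 to 173 ± 2.05 TPM, Eda2r from 11.3 ± 0.825 to 20.9 ± 0.921 TPM and Zmat3 from 23.2 ± 0.312 to 41.8 ± 1.51 TPM. Gtse1, also a mitotic gene, fell from 81.9 ± 3.81 to 24.9 ± 2.01 TPM. Of 16 apoptosis regulators, 6 rose, 4 fell and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.282). The proapoptotic Bax rose by 0.43 and Bak1 fell by 0.82 on the log2 scale, and the antiapoptotic Mcl1 fell by 0.39.

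Of 17 integrated stress response genes, 1 rose, 10 fell and 6 did not pass, also when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0245; adjusted p = 0.277 with an estimated correlation), a call lost with a filter of 5 TPM (adjusted p = 0.0513). The members that fell most, the serine and folate enzymes Shmt2 and Mthfd2 and the asparagine synthetase gene Asns, fell by 1.44, 0.92 and 0.86 on the log2 scale, and Nupr1 by 0.76. In the unfolded protein response list, 2 of 20 rose, 16 fell and 2 did not pass, also when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.011; adjusted p = 0.306 with an estimated correlation). The endoplasmic reticulum genes Canx, Xbp1 and Sec61b fell by 0.93, 0.83 and 0.72, while the chaperone gene Dnajb9 rose by 0.54. Of 22 oxidative stress genes, 3 rose, 14 fell and 5 did not pass, also when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.0117; adjusted p = 0.247 with an estimated correlation). The NRF2 targets Nqo1, Txnrd1 and Gclc fell by 1.90, 1.48 and 1.11, and Txnip, an inhibitor of thioredoxin, rose from 61.7 ± 0.971 to 141 ± 1.12 TPM. Of 15 heat shock genes, 1 rose, 12 fell and 2 did not pass, also when adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.00981; adjusted p = 0.252 with an estimated correlation). The cochaperone genes Stip1, Hsph1, Dnajb1 and Fkbp4 fell by 1.16, 0.98, 0.79 and 0.78.

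Metabolic groups moved in both directions. All 22 tested cholesterol synthesis genes fell, also when adjusted over the list alone, with a median of -0.94 (camera adjusted p = 3.76e-10; adjusted p = 0.195 with an estimated correlation). Fdps, farnesyl diphosphate synthase, fell from 23.3 ± 0.996 to 5.71 ± 0.615 TPM, Tmem97 from 52.4 ± 1.62 to 17.5 ± 0.344 TPM, Hsd17b7 from 58.4 ± 4.29 to 23.2 ± 0.857 TPM and the mevalonate kinase gene Mvk from 175 ± 15.3 to 73.7 ± 4.03 TPM. Of 50 cytosolic ribosomal protein genes, 45 rose, none fell and 5 did not pass (46 rose when adjusted over the list alone), with a median of 0.43 (camera adjusted p = 1.08e-16; adjusted p = 0.247 with an estimated correlation). Rps6, Rpl37 and Rps7 rose by 0.77, 0.73 and 0.70 on the log2 scale. Of 33 nuclear genes of the respiratory chain, 1 rose, 26 fell and 6 did not pass (1 and 28 when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 4.28e-05; adjusted p = 0.252 with an estimated correlation). Uqcrc2 fell from 233 ± 1.19 to 131 ± 6.69 TPM and Atp5b from 977.4 ± 5.28 to 563.2 ± 5.69 TPM, and Atp5o and Ndufb8 fell by 0.92 and 0.79. Of the 13 transcripts of the mitochondrial genome, only mt-Co1 passed in the main test, at 27232 ± 1867 TPM in the controls and 32372 ± 1817 TPM under DTPA (adjusted p = 0.0185), and none when adjusted over the list alone. The call of mt-Co1 was lost under quantile normalization (adjusted p = 0.729), without a filter on low values (0.529) and without control replicate 1 (0.0659) or 2 (0.0696). The list did not pass (camera adjusted p = 0.153), but did without control replicate 3 (adjusted p = 0.0459).

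The remaining lists did not pass. Of 17 hypoxia genes, 5 rose, 5 fell and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.844), with a median of -0.07, a mean of -0.04 and an upward test; Pdk1 and Tpi1 fell by 1.05 and 1.00 and P4ha1 and Hk2 rose by 0.80 and 0.73. Of 29 autophagy and mitophagy genes, 10 rose, 6 fell and 13 did not pass, also when adjusted over the list alone. That list did not pass on the deposited scale (camera adjusted p = 0.131) and rose with median-of-ratios size factors (0.0355) and quantile normalization (0.0259). Its members Ulk1, Atg14, Tfeb and Pink1 rose by 0.84, 0.79, 0.78 and 0.51. Of 12 copper handling genes, 1 rose, 5 fell and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.445), and Atp7b, Sco1, Cox19 and Cox11 fell by 0.60, 0.57, 0.53 and 0.41. Of 8 interferon response genes, 1 rose, 3 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.844); Ifi35, Stat2 and Irf9 fell by 0.73, 0.44 and 0.36 and Bst2 rose by 0.42. Altogether 15 of 28 lists passed, 5 upward and 10 downward, and none of them with an estimated correlation. The G1/S, G2/M and cholesterol lists also passed in each of the 9 other splits of the 6 libraries into 3 and 3, which keep part of the DTPA difference, the ribosomal list in 8, and 7 of the 15 in none.

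**Figure D3:**
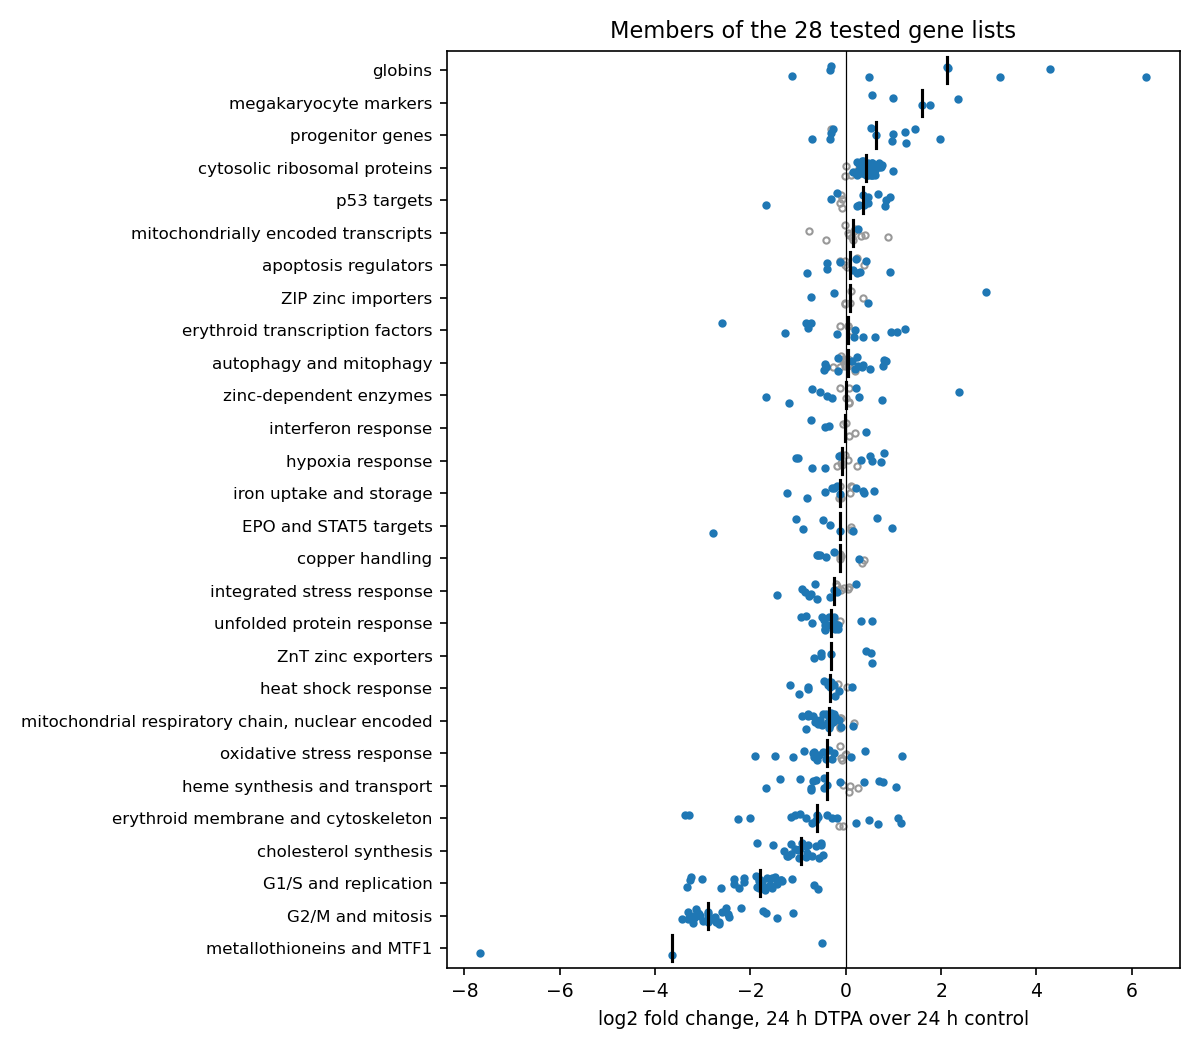
Log2 fold change of each tested member of the 28 lists between DTPA and control at 24 h (3 libraries each); filled points passed the limma test at an adjusted p under 0.05, open points did not, and black bars mark the list medians, from 2.12 for the globins to -3.65 for the metallothionein list.

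The change with differentiation under control zinc was read against the single library at 0 h, so each value rests on that library. There was no undifferentiated library at 24 h, so differentiation cannot be told apart from 24 h of culture or from estradiol itself. Globin and heme synthesis genes mostly rose, and progenitor and G1/S genes mostly fell. Among 11906 tested genes, 1794 were higher and 2894 lower at 24 h (limma, adjusted p under 0.05 and at least 2-fold). The median log2 fold change of all genes was -0.22 on the deposited scale, -0.07 with median-of-ratios size factors, which gave 2057 higher and 2429 lower genes, and -0.03 with quantile normalization, which gave 2228 and 2367. Without the minimum fold, 8863 genes passed, 3675 of them higher. The largest rises were those of Csf2rb2 and Csf2rb, which encode near-identical subunits of cytokine receptors and may share reads, from 1.39 to 1528 ± 129 TPM and from 5.26 to 1053 ± 68.6 TPM. Rogdi rose from 8.81 to 1335 ± 32.1 TPM, Btn1a1, encoding butyrophilin, from 2.83 to 447 ± 17.2 TPM, the amino acid transporter gene Slc38a5 from 3.47 to 495.2 ± 7.79 TPM, and the water channel gene Aqp8 from 1.61 to 229 ± 5.24 TPM. Tubb1 and Tmcc2 rose by 6.23 and 5.85 on the log2 scale, and Mir451a, whose microRNA is abundant in red cells and whose counted exon is 72 bp, was listed at 0 at 0 h and at 142 ± 20.4 TPM at 24 h. The 10 largest rises and the 10 largest falls each included 1 unnamed gene, in the falls the third largest, Gm6093, from 260 to 1.8 ± 0.254 TPM. Among the largest falls were the progenitor genes Lyl1, from 349 to 1.9 ± 0.673 TPM, and Myb, from 139 to 0.617 ± 0.085 TPM, and Nefh, from 324 to 1.72 ± 0.178 TPM. Car1 fell from 4453 to 88.5 ± 6.47 TPM and Srm, spermidine synthase, from 578 to 13.7 ± 0.951 TPM; Ptpn7, Ces2g, Dctd and Tfap4 fell with log2 fold changes of -5.71, -5.79, -5.39 and -5.25.

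Among the erythroid lists, all 8 tested globin genes rose with differentiation, with a median of 2.74, above all of 10000 matched random lists (percentile 100). The adult alpha genes summed to 2935 TPM at 0 h and 17819 TPM in the controls, and the adult beta genes to 6190 and 31802 TPM; Hbb-y and Hba-x were listed at 0 at 0 h. Of 19 heme genes, 10 rose and 2 fell (median 1.17, percentile 99.9), led by Alas2, the first enzyme of erythroid heme synthesis, from 34.1 to 1937 ± 61.6 TPM, and Abcb10, Hmox1 and Ppox rose by 3.97, 3.23 and 2.96. Of 23 membrane and cytoskeleton genes, 12 rose and 4 fell (median 1.00, percentile 99.9). Dmtn rose from 1.74 to 98.8 ± 1.95 TPM, Slc4a1 from 45.6 to 770.3 ± 3.71 TPM and Sptb, beta spectrin, from 113 to 1042 ± 32.3 TPM, while the adhesion gene Cd44 fell by 3.98. Of 29 autophagy genes, 15 rose and 1 fell (median 1.04, percentile 100), with rises of 3.21, 2.98, 2.97 and 2.55 for Map1lc3a, Gabarap, Wipi1 and Atg9a. Of 19 p53 targets, 6 rose and 2 fell (median 0.75, percentile 99.4), among them Btg2, from 18.1 to 881 ± 18.1 TPM, with Trp53inp1 and Sesn2 up by 3.97 and 1.73 and Aen down by 1.26. Of 9 interferon response genes, 5 rose and 1 fell (median 1.05, percentile 99.8), with Irf7, Parp14, Irf9 and Bst2 up by 2.76, 2.72, 1.66 and 1.09, the last under 2-fold with a pseudocount of 5 (0.81).

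Progenitor genes went down, 10 of 16 with 1 up (median -1.92, percentile 0). Kit fell from 138 to 7.41 ± 0.207 TPM and Myc from 474 to 14.9 ± 0.164 TPM, and Rgs18 with a log2 fold change of -5.07. Of 30 G1/S genes, 1 rose and 23 fell (median -1.64, percentile 0), with Cdt1, Mcm6, Uhrf1 and Mcm10 down by 3.25, 2.79, 2.68 and 2.61. The 30 G2/M genes behaved differently: 3 rose and 5 fell (median -0.12, percentile 49.5). Nusap1 was up by 2.13 and Aurkb and Cdk1 were down by 1.77 and 1.74. Of 50 ribosomal protein genes, none rose and 19 fell (median -0.91, percentile 0.01), with Rps13, Rpl14 and Rps2 down by 1.41, 1.39 and 1.35. Of 15 heat shock genes, 1 rose and 9 fell (median -1.23, percentile 0.14), with log2 fold changes of -3.02, -2.75, -2.28 and -2.18 for Hspd1, Hsp90ab1, Fkbp4 and Hsp90aa1. Of 8 megakaryocyte markers, 1 rose, Tubb1, and 5 fell (median -1.71, percentile 0.08), with Gp5, Nbeal2 and Pf4 down by 4.18, 2.85 and 2.68. All 4 tested myeloid and mast cell markers fell (median -1.62, percentile 1.39); Cpa3 was at 7.25 TPM at 0 h and listed at 0 in the controls, and the other 3, Gzmb, Ms4a2 and Cd68, were under 2-fold with a pseudocount of 5 (-0.73, -0.31 and -0.64), Cd68 also with median-of-ratios size factors (-0.96) and quantile normalization (-0.73).

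The zinc lists did not stand apart with differentiation, at percentiles of 16.7 for the importers (2 rose and 3 fell of 9), 65.9 for the exporters (1 and 1 of 7), 88.1 for the metallothionein list (1 and 0 of 3) and 26.5 for the zinc enzymes (2 and 5 of 16). Slc39a8 rose from 42.7 to 298 ± 7.83 TPM, while Slc39a10 and Slc39a6 fell by 4.15 and 1.14 on the log2 scale and Slc39a11 from 12.5 to 1.25 ± 0.401 TPM; the fall of Slc39a6 was under 2-fold with median-of-ratios size factors (-0.98), quantile normalization (-0.82) and a pseudocount of 5 (-0.85). Slc30a9 and Mtf1 rose by 1.13 and 1.10, both under 2-fold with a pseudocount of 5 (0.997 and 0.91), Slc30a2 fell by 2.08, and among zinc enzymes Sord rose by 2.88 and Ada fell by 2.76. Other lists lay at percentiles of 97.6 for cholesterol synthesis (6 rose and 2 fell of 22, Fdps, Ebp and Srebf2 up by 1.71, 1.69 and 1.48 and Tmem97 down by 1.65), 94 for the oxidative stress response (7 and 4 of 22, Bach1 and Cat up by 4.24 and 2.17, Me1 down by 2.55), 92.1 for erythropoietin and STAT5 targets (5 and 3 of 12, Erfe and Gadd45g up by 3.09 and 2.98, Podxl and Osm down by 3.99 and 2.94) and 82 for erythroid transcription factors (4 and 3 of 17, Zfpm1 and Foxo3 up by 2.27 and 1.94, Bcl11a and Cited2 down by 2.91 and 1.79). Copper handling lay at 74.5 (3 and 1 of 12, Atp7a and Slc31a1 up by 2.69 and 2.06, the other 2, Slc31a2 and Sco1, under 2-fold with a pseudocount of 5 at 0.77 and -0.86, and Sco1 under quantile normalization at -0.85), apoptosis regulators at 67.6 (3 and 4 of 17, Bcl2l1 up by 2.24 and Bid down by 2.92) and mitochondrial transcripts at 38.8 (none called of 13). Iron uptake and storage lay at 32.2 (5 and 3 of 17, Ncoa4 and Ftl1 up by 3.30 and 1.76, Tfr2 down by 2.96), the unfolded protein response at 21.6 (3 and 3 of 20, Dnajb9 and Xbp1 up by 2.74 and 1.89, Pdia4 and Hyou1 down by 1.75 and 1.48) and the respiratory chain at 7.64 (0 and 5 of 33, with Cyc1 down by 1.24 and Sdhb, Ndufa10 and Sdha by 1.09, 1.07 and 1.06, these 3 under 2-fold with median-of-ratios size factors and Sdha also without globin genes). The hypoxia list lay at 6.94 (2 and 8 of 19, Pfkfb4 up by 3.92, Vegfa, Pdk1 and Ldha down by 4.14, 3.70 and 3.67) and the integrated stress response at 6.89 (5 and 7 of 17, Ppp1r15a and Ddit3 up by 3.81 and 2.35, Trib3 and Shmt2 down by 2.27 and 2.13). No lymphoid marker was tested.

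Whether DTPA moved the genes that change with differentiation was asked by setting both comparisons side by side. Some strongly induced erythroid genes were far lower under DTPA, such as Slc4a1, Dmtn and Erfe, and some strongly repressed genes were higher, such as the progenitor genes Kit and Myb and the zinc genes Car1 and Slc39a10. Others went further in the direction of differentiation, such as Hbb-bh1, Hbb-y and Aqp8, which rose from 229 ± 5.24 to 644 ± 15.1 TPM under DTPA, and the replication genes Mcm5 and Mcm6, which fell in both comparisons. Alas2, up 5.79 with differentiation, was higher still under DTPA, at 2538 ± 41.4 TPM. Among 10959 genes tested in both, 1787 rose and 2392 fell with differentiation. Of those that rose, 508 were higher and 668 lower under DTPA, where independent lists would share 379 and 662. Of those that fell, 534 were higher and 946 lower, where independent lists would share 508 and 886. Under quantile normalization the first overlap was 836, where independent lists would share 632, and the last was 700, where they would share 559. Log2 fold changes of the 2 comparisons correlated across genes at 0.0214, with a covariance of 0.0181. In simulated unchanged groups the correlation was -0.363 and the covariance -0.0116, a difference in covariance of 0.0297. Those groups hold only noise, so their correlation does not show how far shared controls moved the observed one. Simulated unchanged groups hold almost no calls, and their overlaps of at most 1 therefore say nothing on the sharing of controls. With 1 control used for differentiation and the other 2 for DTPA, a test added after the results were seen, genes that rose and were higher were 1.37 to 1.38 times those of independent lists, against 1.34 with shared controls. The other 3 overlaps were 0.979 to 1.09 times those of independent lists, and the correlations were then 0.0404, 0.0413 and 0.0438.

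In the comparison of DTPA at 24 h with 0 h, 1802 genes were higher and 3316 lower. Over the 4688 genes called with differentiation under control zinc, the change from 0 h to DTPA followed the change from 0 h to control with a slope of 1.01, 0.988 for those that rose and 1.02 for those that fell. Both changes take off the same single 0 h library, and a slope of 1 is also what no effect of DTPA would give, so the slope does not show how DTPA acted. In 313 of the 4688, Slc4a1 and Slc39a10 among them, the change under DTPA was less than 0.5 times that in the controls. For Slc4a1 the log2 changes were 4.05 in the controls and 0.67 under DTPA, and for Slc39a10 they were -4.15 and -1.21. For Hbb-bh1 they were 3.00 and 9.31.

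**Figure D4:**
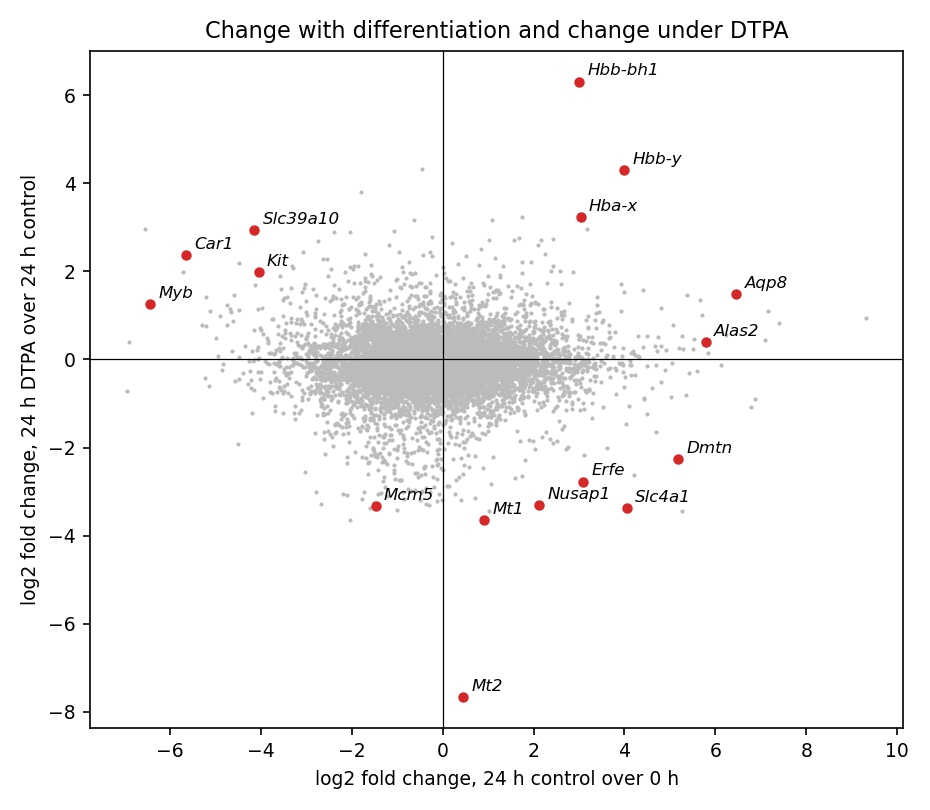
Log2 fold change between 24 h control and 0 h (horizontal) and between 24 h DTPA and 24 h control (vertical) for the 10959 genes tested in both (grey points), with 16 genes named in red; there are 3 libraries per group at 24 h and 1 at 0 h. Hbb-bh1 rose in both, Slc4a1 rose with differentiation and fell under DTPA, and Slc39a10 fell with differentiation and rose under DTPA.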

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

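The test with voom on estimated reads was chosen after seeing the data. The count of genes changed by DTPA, 6474, lay between 5837 and 6627 over the other pseudocounts, filters, scalings, variance models, the 7-library fit and voom, and between 5716 and 6110 without each library at 24 h; 5144 of the 6474 calls held, in the same direction, in all 6 fits that leave a library out. With a minimum of 1.5-fold it was 2569, 1002 higher and 1567 lower, because the minimum removes small changes. The replicate numbers did not pair the libraries: same-numbered libraries deviated from their group means with correlations of -0.0103, 0.0242 and -0.00964, and the replicate block gave 6162 genes, 2274 higher and 3888 lower, and 15 lists. The block ended the calls of Slc30a2 and Cd68. Without a minimum fold, the count for differentiation was 8863, 3675 higher and 5188 lower, again by construction; over the other settings it lay between 3240 with a pseudocount of 5 and 5099 with voom. Genes that rose with differentiation and were higher under DTPA numbered 836 under quantile normalization in place of 508, where independent lists would share 632 in place of 379. Lists passing went from 15 to 0 with an estimated correlation, 25 with the directional fry test and 27 with its mixed test, which asks only whether members move. The directional fry test put 3 lists that did not pass on the opposite side of camera: iron uptake and storage (median log2 fold change -0.112, fry adjusted p = 0.00724), erythroid transcription factors (0.0495, 0.00446) and the hypoxia response (-0.0736, 0.0435); the cause was not tested. Among the lists that passed, and beyond those named with their results, medians moved by over 1.5 times with the calls kept for progenitor genes (0.98 with a filter of 5 TPM, 1.00 with voom), the integrated stress response (-0.15, median-of-ratios), and under quantile normalization the unfolded protein response (-0.16), heat shock (-0.20) and respiratory chain (-0.21) lists. For 250 results on single named genes, Slc39a10 among them, 4091 refits were made. Of these refits, 4044 kept direction and side of the threshold, 46 lost the call, 1 gained it and 0 reversed. The depth of 17.58 to 21.19 M reads leaves genes under 1 TPM resting on few reads, and 1 library at 0 h leaves differentiation without a replicate of its start.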

Other observations

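Groups of genes beyond the fixed lists were looked at after the results were seen, by the start of their symbols. Proteasome subunits, which degrade tagged proteins, were lower under DTPA: 32 of 35 fell and 0 rose, with a median log2 fold change of -0.45 (-0.28 under quantile normalization; camera adjusted p = 1.81e-07, adjusted p = 0.143 with an estimated correlation). Mitochondrial ribosomal proteins fell in 54 of 80 genes and rose in 4, with a median of -0.37 (-0.22 under quantile normalization; camera adjusted p = 4.45e-05, adjusted p = 0.143 with an estimated correlation), the opposite direction to the cytosolic ribosomal proteins. Aminoacyl-tRNA synthetases fell in 19 of 35 and rose in 3 (median -0.26, -0.17 under quantile normalization, camera adjusted p = 0.01, adjusted p = 0.313 with an estimated correlation). The 268 Zfp genes, a large group of zinc finger proteins, moved in both directions, with 71 up, 65 down and a median of 0.02 (0.13 under quantile normalization; camera adjusted p = 0.0379, adjusted p = 0.597 with an estimated correlation). Of 8 chaperonin subunits 1 rose and 5 fell (median -0.26, -0.12 under quantile normalization, camera adjusted p = 0.2), and of 2 tested histone genes 1 rose and 1 fell (median 1.04 on both scales, camera adjusted p = 0.568).

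Of the tests below, only the numbers of genes and lists called in other splits were chosen before their result was seen. The 6 libraries at 24 h can be split into 3 and 3 in 10 ways. Only 1 of the 10, the real one, called as many genes (6474, against 0 in the highest other), and only 1 called as many lists (15, against 7 in the highest other). With 10 splits the share cannot go under 0.05. The 9 other splits called 4 to 7 lists each with camera at the preset correlation although they called no gene. In a look added after the results were seen, the G1/S, G2/M and cholesterol lists passed in 9 of the 9, the ribosomal list in 8, the respiratory chain list in 5, the megakaryocyte list in 3, the mitochondrial transcripts in 2, and the heat shock and integrated stress response lists in 1 each. Each of these splits sets 2 libraries of 1 treatment and 1 of the other against the reverse, so part of the DTPA difference stays in it. A list that passed there is therefore not shown to be a false call. Of the 15 lists called between DTPA and control, 7 passed in 0 of the 9: globins, metallothioneins, the erythroid membrane, progenitor genes, p53 targets, the unfolded protein response and the oxidative stress response.

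Slc39a10 was the zinc importer gene with the largest rise under DTPA. Retention of all genes that fall with differentiation is argued against, since the median log2 fold change under DTPA of the 2392 genes that fell was -0.12. Their middle 95% ended at 1.41, and Slc39a10 lay at percentile 99.87. A gene can regain only what it lost, and the 2392 include genes that fell by little more than 1 on the log2 scale. The percentile therefore does not decide whether genes with large falls, Slc39a10 among them, were retained. Thin counts are argued against, as the lowest library held an estimated 37 reads. DTPA binds iron too. Tfrc, whose transcript is stabilised in iron-poor cells, had a log2 fold change of -0.148 (95% interval -0.279 to -0.0167, limma adjusted p = 0.0543), below the 0.5 set afterwards as the least for iron shortage. The level of 1 transcript also depends on how much of it is made, so it does not decide on iron shortage. A response of Slc39a10 to low zinc, alongside the loss of metallothionein transcripts, may be the biological reading, as a hypothesis. It leaves open iron and other metals bound by DTPA, and adding back zinc or iron would test it. Retention is open too: Kit, Myb and Car1, which fell with differentiation, were higher under DTPA, and Gata1 reads were lower. Of all genes that fell, 534 were higher and 946 lower. Of the ZnT exporter genes, 3 were higher and 4 lower, and Slc30a1, the main zinc exporter of the plasma membrane, was among the higher ones.

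Embryonic globin transcripts rose far more in fold than adult ones under DTPA. In amount, the adult beta genes gained more, from 31802 to 52380 TPM, against 53.7 to 4319 TPM for Hbb-bh1, the most abundant embryonic one. Reads misassigned from adult globins are argued against, because the smallest lower 95% bound of the 3 embryonic log2 fold changes was 2.94 and the largest upper bound of the adult sums 0.997. A common rise of all globins is argued against by the upper bound of the adult alpha sum, -0.299, and the TPM scaling by the smallest rise under the other scalings, 3.27. A shift toward the embryonic globin program under zinc restriction may be proposed as a hypothesis, and Bcl11a, a known repressor of embryonic globin genes, fell from 6.5 ± 0.188 to 3.35 ± 0.245 TPM (limma adjusted p = 2.07e-04), which was not tested as a cause. Embryonic globin transcripts after zinc is added back to cells in DTPA would test it.

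Genes that change with differentiation moved both ways under DTPA, and those that rose and were higher were more than independent lists would share, 508 against 379. The overlap of independent lists does not allow for how readily a gene is called under DTPA. Of the genes that rose, 28.4% were called higher and 37.4% lower, while 58.1% of all 11147 genes tested under DTPA were called in either direction. Part of the excess may therefore come from more frequent calls, which was not tested. The TPM scaling is argued against as the source of this excess, since the smallest ratio over 4 scalings was 1.27, above a limit of 1.2 set after the values were seen. Noise of the shared controls is argued against too, since it pushes the 2 comparisons apart and so works against such an excess. In simulated unchanged groups it gave a covariance of -0.0116, where the observed covariance was 0.0181. The smallest ratio with disjoint controls was 1.37. The other overlaps depended on the scaling: genes that fell and were lower were 1.07 times those of independent lists on the deposited scale and 1.25 times under quantile normalization, and genes that fell and were higher 0.907 times under quantile normalization. A block of the whole program is not decided. It would lower the genes that rose, which were called against the single 0 h library. Over 4 scalings, those that were lower were 0.94 to 1.01 times the share of independent lists, and those higher 1.27 to 1.34 times. On the deposited scale, 668 were lower and 508 higher. A block alone would not raise the 508, but they are the pattern to be explained and leave the rest undecided. The smallest ratio of genes that fell and were lower, 1.07, did not decide a block either. An advance of the whole program is not decided, as any broad effect fills all 4 overlaps and the smallest ratio was 0.94 for genes that rose and were lower. No account of maturation is offered.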
